A study of Homo sapiens with 16 samples.

How the data were processed

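RNA was sequenced from primary human retinal microvascular endothelial cells (HRMVECs), which line the small vessels of the retina and which the labels describe as a pool of several donors. Per the labels' protocols, the cells were left untreated or treated for 24 h with norrin at 200 ng/ml, with nutlin-3 at 10 µM, or with both, and every culture held 0.1% DMSO. Norrin is a secreted ligand that activates Wnt/beta-catenin signaling through the receptor FZD4. Nutlin-3 is a small molecule that blocks the binding of MDM2 to p53 and so stabilizes p53. The 16 libraries form 4 groups of 4. Total RNA was freed of ribosomal RNA and made into strand-specific paired-end libraries, per the labels' protocols.

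The submitters' processing notes name STAR, an aligner, without a version. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here, so no coordinates are reported. Per the file headers, the authors' deposited table holds estimated counts per gene for each library, which need not be whole numbers. Between 3.18% and 3.77% of the values in a library had a fraction. The authors' deposited table also holds 1 RPKM value per group (per the file headers, with no spread) and the authors' fold (ratio) between groups. The RPKM and ratio columns were used only where a sentence names the authors' deposited table. Because the strand setting and the handling of shared reads are unknown, genes that overlap another gene or belong to a family of near-identical copies are uncertain. Among the named genes, ACTA2, AXIN2, FANCA, ICAM1, NEURL2, PLAU and SPTB share at least 20% of their exon bases with another gene in the GENCODE 29 annotation. The histone genes and the CXCL1 family also have near-identical copies.

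The table held 38135 lines. 15 lines without counts were left out, and so was 1 line without a gene name, which held between 0.00084% and 0.0055% of a library's counts. 27 lines carried a date in place of a gene symbol and were kept under neutral names, and none of them is named here. 94 lines shared a name with another line and were summed by name, which left 38068 gene names. The estimated counts were rounded to whole numbers before testing. Total counts per library ranged from 30655989 to 42555694, above the read number that the labels state. Genes of the Y chromosome, XIST and TSIX entered the fits and were not tabulated per sample.

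Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors, filterByExpr by group, and Benjamini-Hochberg adjustment with a threshold of 0.05. All 16 libraries shared 1 fit with a mean per group. The 16437 genes that passed the filter were tested in 6 comparisons: nutlin-3 against untreated, norrin against untreated, the combination against untreated, against nutlin-3 and against norrin, and the interaction, which is the norrin effect with nutlin-3 minus the norrin effect without it. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM, the counts relative to library totals scaled by the TMM factors. The common biological coefficient of variation was 0.343. For genes with an average above 3 log2 CPM, the median standard error of a log2 fold change was 0.243 for nutlin-3 against untreated and 0.242 for norrin against untreated.

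22 gene lists fixed before the data were examined were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2, 2-sided, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over all 132 list tests. The lists covered p53 targets, G2 and mitosis, DNA replication, replication-dependent histones, Wnt/beta-catenin targets, norrin receptor and Wnt pathway components, the blood-retina barrier, endothelial identity, tip cells and angiogenesis, the Notch pathway and arterial genes, venous genes, TGF-beta and BMP responses, inflammatory activation, interferon responses, cholesterol synthesis, integrated stress and unfolded protein responses, hypoxia, immediate early genes, and markers of pericytes, smooth muscle and fibroblasts, of retinal glia, neurons and pigment epithelium, of leukocytes, and of lymphatic endothelium. Camera was repeated with an estimated correlation and with the replicate number as a block. Fry was run beside it, by its directional test unless stated. Some genes belong to more than 1 list. Members below the filter were not tested, and counts for a list are of its tested members, such as 13 of 22 Wnt/beta-catenin targets.

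The rule for named genes was also fixed before the data were examined. In each comparison it took the 10 genes with the largest increase and the 10 with the largest decrease among genes past the threshold whose sample values did not overlap between the groups and whose mean was at least 1 log2 CPM. It added up to 4 members of each list with the smallest p, and 15 fixed genes of the p53 and norrin pathways and of the endothelium. Some genes that the rule allows are not reported here. A gene outside this rule is said to have been chosen after its values were seen.

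The alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no filter or a CPM of at least 1 in at least 4 samples, the replicate number as a block, only the groups compared, leaving out each library in turn, an adjusted p under 0.01, and a minimum absolute log2 fold change of 1. Covariates for the trend of counts with transcript length and GC content, the removal of 2 libraries that stood apart, and the removal of ribosomal RNA genes were added after the data were seen. The length and GC slope of each library is the coefficient of log2 CPM on the scaled log2 length and GC content of the longest GENCODE 29 transcript of a gene, fitted over the 8797 genes with a length and a mean above 3 log2 CPM. 87.8% of the tested genes had a length.

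The tests were tested on simulated counts drawn from each gene's mean over all libraries, its dispersion and the real library sizes. In these, 200 genes per agent, all with a mean above 1 CPM, were changed 1.5, 2 or 4-fold. Genes were drawn independently, without the transcript-length trend of the libraries. In the simulated norrin against untreated comparison over 16169 genes, edgeR called 2 of 60 genes changed 1.5-fold, 17 of 80 genes changed 2-fold and 54 of 60 genes changed 4-fold. In the simulated nutlin-3 against untreated comparison it called 1 of 60, 26 of 80 and 53 of 60. Nothing in the labels says that the 4 libraries of a group came from separate cell preparations, so p-values measure only the spread between these samples, which may be technical. Counts of reads from 2 libraries of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 18.2, so no library was counted as a repeat of another. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.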

Results

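RNA was measured in HRMVECs after 24 h without treatment, with norrin, with nutlin-3, or with both, in 4 libraries per group. Total counts per library ranged from 34364945 to 39808535 in the untreated group, from 31092405 to 42555694 with norrin, from 30655989 to 35681831 with nutlin-3 and from 32709592 to 33850026 with the combination. The first principal component of all tested genes held 49.9% of the variance and separated the 8 libraries given nutlin-3 from the other 8. The libraries of a group also differed among themselves: after the group means were removed, 46.1% of the variance lay on 1 component, which followed transcript length across libraries with r = 0.92. The slope of log2 CPM on transcript length ranged from −0.623 to 0.234. Ribosomal RNA genes held a mean of 8.14% of counts in untreated and 2.48% in norrin libraries (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows; 0.214 after Benjamini-Hochberg adjustment over 15 such tests).

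**Figure D1:**
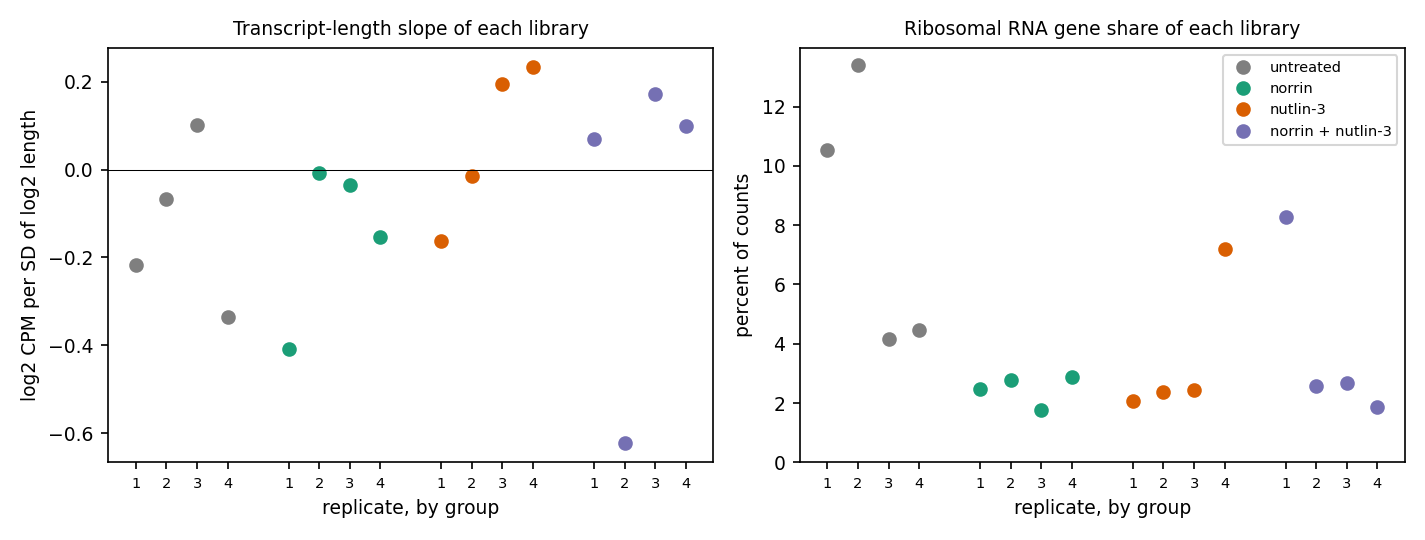
Slope of log2 CPM on transcript length (left, per SD of log2 length) and percent of counts in ribosomal RNA genes (right) in each of the 16 libraries, colored by group. The slope spans −0.623 to 0.234, and the ribosomal share reaches 13.4% in an untreated library and stays at or under 2.88% in the norrin libraries.

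The comparison of nutlin-3 with untreated cells asked what stabilizing p53 does to retinal endothelium. MDM2, which encodes the p53 ubiquitin ligase that nutlin-3 blocks and is itself a p53 target, was 4.86 ± 0.57 log2 units higher, at 692 ± 323 CPM (mean ± SD, n = 4) against a background of 23.7 ± 13.9 CPM in untreated cells. The cell cycle inhibitor CDKN1A rose by 3.82 ± 0.24 log2 units, from 103.4 ± 31.1 to 1465 ± 167 CPM, and the death receptor FAS by 4.39 ± 0.23. Among genes with a mean of at least 1 log2 CPM and no overlap between the groups, the largest increases were in RRAD (8.98 ± 0.58), which encodes a small GTPase, and DRAXIN (7.86 ± 0.57), which encodes an axon guidance factor and Wnt antagonist. The proliferation marker MKI67 fell by 7.23 ± 0.43 log2 units, from 180.4 ± 82.5 to 1.2 ± 0.451 CPM. MDM4, which encodes a p53 inhibitor, did not pass (0.17 ± 0.34), at 13.3 ± 2.99 CPM untreated and 14.97 ± 6.65 CPM with nutlin-3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 7.97e-06 for MDM2, 6.14e-09 for CDKN1A, 9.22e-10 for FAS, 8.86e-09 for RRAD, 2.72e-08 for DRAXIN, 3.89e-09 for MKI67 and 0.736 for MDM4. In the authors' deposited table, the fold of nutlin-3 over untreated was 32.5 for MDM2, 15.9 for CDKN1A and 0.00797 for MKI67.

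Of 16437 genes, 2181 were higher and 2254 lower with nutlin-3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), together 27% of those tested, and 1460 of the higher and 1353 of the lower genes changed at least 2-fold. The count of 4435 rose to 6655 with transcript-length and GC covariates. The sample values of 4583 genes (27.9%) did not overlap between the groups, where chance gives 2.86%. Library totals in place of TMM factors shifted the median log2 fold change of all genes to 0.137 in this comparison, 0.173 for norrin against untreated, 0.122 for the combination against untreated and −0.203 for the interaction, so small changes are relative to the scaling. Next by increase among genes with a mean of at least 1 log2 CPM and no overlap were NSG1, ETV7, EPS8L2, NUPR1, ULBP1, TAF7L, SPTB and NEURL2, between 5.22 ± 0.26 (NEURL2) and 6.28 ± 0.33 (NSG1). ULBP1 (5.80 ± 0.51), a ligand of the natural killer cell receptor NKG2D, has close relatives that can share reads. NEURL2 shares 79.8% and SPTB 23% of its exon bases with a gene on the other strand, so both are uncertain. The 10 largest decreases among such genes were in SPC25 (−8.69 ± 0.64), ASPM, MKI67, PIMREG, KIF18B, NCAPH, PBK, CDCA2, KIF20A and SHCBP1 (−6.43 ± 0.29), most of them mitotic genes; lower-level genes, GJA4 and MCM10 among them, fell as far.

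All gene lists fixed in advance were tested for movement relative to other genes by camera. Of the 50 tested p53 target genes, 47 were higher, 0 lower and 3 not passing, and 49 were higher adjusted over the list alone; their median log2 fold change was 2.21 (adjusted p = 1.6e-31). CMBL rose by 3.58 ± 0.17 and PIDD1 by 3.29 ± 0.20. All 36 G2 and mitosis genes were lower, also adjusted over the list alone, with a median of −5.15 (adjusted p = 3.96e-46), among them TPX2 (−4.88 ± 0.21) and TTK (−6.17 ± 0.28). Of 38 DNA replication genes, 37 were lower and 1, LIG1, was higher, also adjusted over the list alone, with a median of −3.02 (adjusted p = 1.78e-35). MCM10 fell by 8.03 ± 0.40, EXO1 by 4.87 ± 0.29, ORC1 by 4.40 ± 0.24 and MCM4 by 3.19 ± 0.18. Of 23 tested replication-dependent histone genes, 13 were lower and 10 did not pass (17 lower adjusted over the list alone), with a median of −2.21 (adjusted p = 2.23e-05, and adjusted p = 0.521 with an estimated correlation). HIST1H4H (−2.86 ± 0.60) and HIST1H1B (−3.43 ± 0.80) were among them, and their near-identical copies leave single members uncertain. With the estimated correlation, the calls for p53 targets, G2 and mitosis, DNA replication, inflammatory activation and Notch pathway genes held, with adjusted p between 0.000281 and 0.0075.

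Inflammatory genes rose with nutlin-3. ICAM1, a leukocyte adhesion molecule, increased by 3.84 ± 0.23 log2 units, from 6.29 ± 0.884 CPM in untreated cells to 90.3 ± 9.90 CPM (n = 4 each; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.16e-09), though it shares 23.6% of its exon bases with a gene on the other strand. The neutrophil chemokine gene CXCL8 rose by 2.91 ± 0.21, TRAF1 by 4.03 ± 0.32 and CXCL1, which has close relatives, by 3.96 ± 0.39. Of 27 inflammatory activation genes, 23 were higher, 2 (SELP and CD40) lower and 2 not passing, with the same counts adjusted over the list alone, and the median was 3.64 (camera adjusted p = 3.91e-15).

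Arterial and Notch pathway genes fell. GJA4, which encodes an arterial connexin, had 1246 reads in the untreated and 2 in the nutlin-3 libraries, a ratio of 601 with a 95% counting interval from 166 to 4960 that covers counting error only. The Notch ligand DLL4 fell by 1.46 ± 0.20, BMX by 1.19 ± 0.15, the Notch modulator MFNG by 1.70 ± 0.22 and IGFBP3 by 2.63 ± 0.34. Of 20 Notch pathway and arterial genes, 1 (JAG1) was higher, 11 were lower and 8 did not pass, with the same counts adjusted over the list alone, and the median was −0.99 (camera adjusted p = 0.000335).

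**Figure D2:**
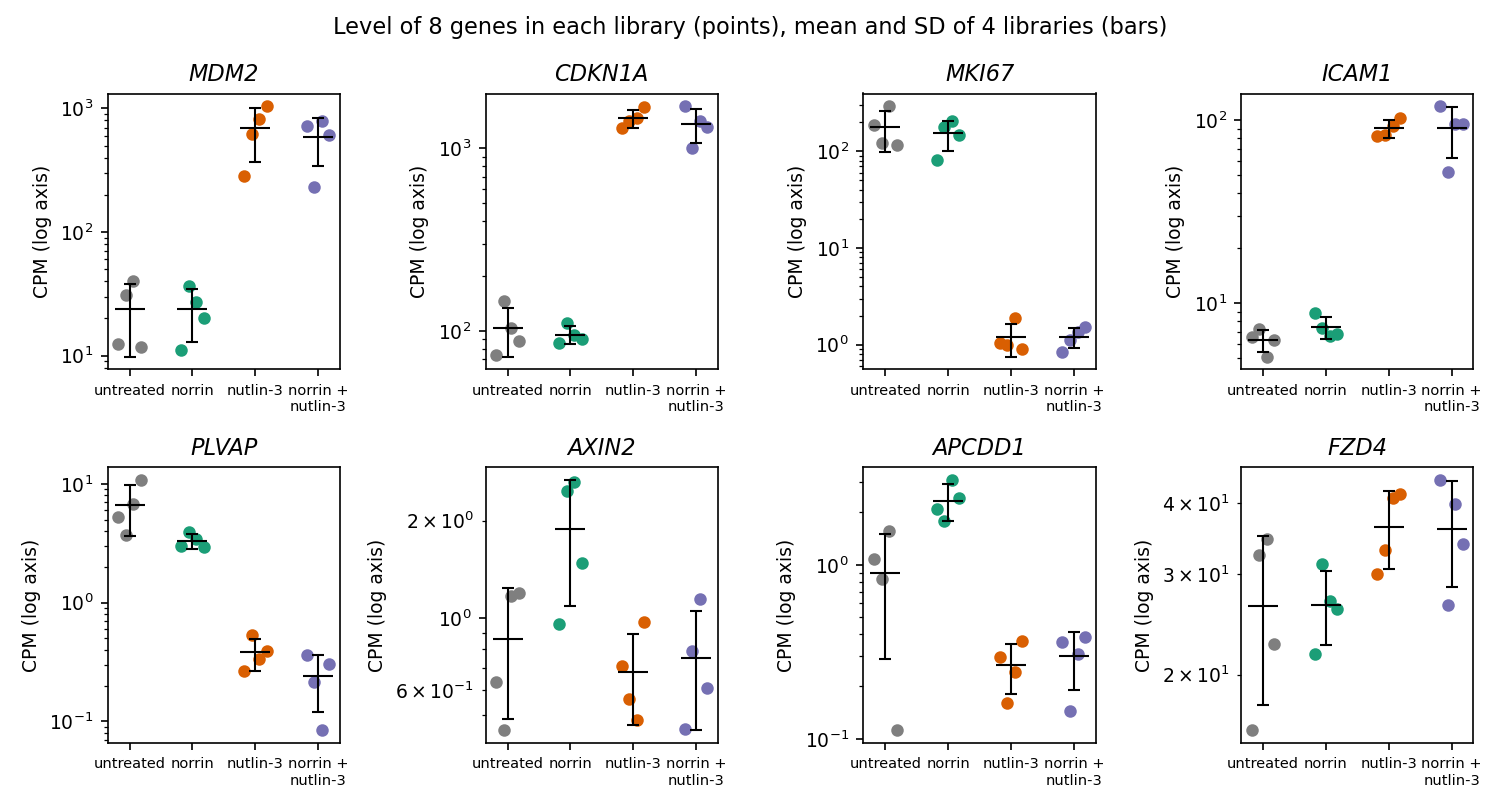
CPM on a log axis of MDM2, CDKN1A, MKI67, ICAM1, PLVAP, AXIN2, APCDD1 and FZD4 in each of the 16 libraries (points) with the mean and SD of the 4 libraries of a group (bars; lower bars that would pass 0 end just above it). MDM2 averaged 23.7 CPM in untreated and 692 CPM in nutlin-3 libraries, and AXIN2 averaged 0.862 CPM in untreated and 1.88 CPM in norrin libraries.

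Single barrier and endothelial genes changed while their lists did not pass. PLVAP, a marker of leaky fenestrated endothelium, fell by 4.11 ± 0.40 with nutlin-3, from 6.69 ± 3.07 to 0.382 ± 0.115 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.46e-07). The efflux transporter gene ABCG2 fell by 3.61 ± 0.32, the lipid transporter gene MFSD2A by 2.43 ± 0.25, SOX18 by 1.93 ± 0.23, SOX17 by 1.07 ± 0.18, NOS3 by 1.5 ± 0.16 and CLEC14A by 1.40 ± 0.17. The tight junction gene CLDN5, at 461 ± 198 CPM untreated and 229 ± 56.5 CPM with nutlin-3, did not pass (−1.01 ± 0.37, adjusted p = 0.0512 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its call depended on the setting: it passed without untreated replicate 3 (adjusted p = 0.0284) and in 7 other settings, with adjusted p between 0.0233 and 0.0491 over those 8. Of 32 barrier genes, 5 were higher, 7 lower and 20 not passing (5 and 9 adjusted over the list alone, camera adjusted p = 0.445). PLVAP is among the 7, so the count and the list test mix this marker of leaky endothelium with genes of a tight barrier. Of 30 endothelial identity genes, 1 was higher, 8 lower and 21 not passing, with 1 higher and 8 lower adjusted over the list alone (adjusted p = 0.216). Of 8 venous genes, 1 (NRP2, 1.40 ± 0.34) was higher and 2 (PLVAP and SELP, −1.97 ± 0.40) were lower, also adjusted over the list alone (adjusted p = 0.366). Of 29 tip cell and angiogenesis genes, 9 were higher and 5 lower, with 10 and 5 adjusted over the list alone (adjusted p = 0.21); PLAU, which overlaps a gene on the other strand, rose by 2.79 ± 0.18 and ESM1 by 1.98 ± 0.29.

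Wnt genes moved in both directions with nutlin-3. The Wnt antagonist gene DKK1 rose by 1.52 ± 0.16 and CD44 by 1.32 ± 0.14, and PORCN, whose product acylates Wnt proteins, rose by 2.35 ± 0.19. FZD8 fell by 1.17 ± 0.19. The norrin receptor gene FZD4, at 26.4 ± 8.70 CPM untreated and 36.4 ± 5.72 CPM with nutlin-3, did not pass (0.46 ± 0.23, adjusted p = 0.153 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment), nor did AXIN2 (−0.33 ± 0.43, adjusted p = 0.59). APCDD1, a Wnt target and antagonist, was lower (−1.77 ± 0.54, adjusted p = 0.0237), and this call was lost without untreated replicate 1 (0.0564) or 3 (0.0747) or nutlin-3 replicate 2 (0.0739) or 3 (0.0646). Of 22 listed Wnt/beta-catenin targets 13 were tested, and 3 were higher, 2 lower and 8 not passing (camera adjusted p = 0.701). Of 33 tested norrin receptor and Wnt pathway components 3 were higher, 5 lower and 25 not passing (camera adjusted p = 0.576). Adjusted over the list alone, 3 targets were higher and 2 lower, and 3 components were higher and 4 lower. LEF1, with 4, 1, 3 and 6 reads in the untreated, norrin, nutlin-3 and combination groups, and NKD1, with 6, 7, 6 and 8, lay below the filter.

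The other lists did not pass by camera in this comparison. Fry's directional test asks whether a list moves up or down by itself rather than relative to other genes. It called 5 lists that camera did not: immediate early genes (adjusted p = 0.000109), TGF-beta and BMP responses (0.00804), markers of pericytes, smooth muscle and fibroblasts (0.0148), cholesterol synthesis (0.0354) and Wnt/beta-catenin targets (0.0372). Fry's mixed test, for movement of members in either direction, passed for every list in this comparison except retinal glia, neuron and pigment epithelium markers (adjusted p = 0.75). The adjusted p values below are by camera. TGF-beta and BMP responses had 7 of 28 members higher and 4 lower (8 and 5 adjusted over the list alone; adjusted p = 0.21), with SMAD6 at −2.10 ± 0.22. Interferon responses had 6 of 33 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.632), with IFIH1 at 1.60 ± 0.21 and OAS1 at −1.02 ± 0.19. Cholesterol synthesis had 1 of 24 higher and 6 lower (3 and 7 adjusted over the list alone; adjusted p = 0.136), with EBP at −1.94 ± 0.38. Hypoxia responses had 7 of 24 higher and 3 lower (8 and 4 adjusted over the list alone; adjusted p = 0.521), with P4HA2 at 2.10 ± 0.27 and LDHA at −1.32 ± 0.24. Immediate early genes had 6 of 18 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0669), with ATF3 at 3.03 ± 0.22. Integrated stress and unfolded protein responses had 4 of 24 higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.844; median 0.011, mean −0.028, test direction down). Markers of pericytes, smooth muscle and fibroblasts had 3 of 13 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.521; median −0.078, mean 0.256, direction up), with NOTCH3 at 4.04 ± 0.58 and ACTA2, which overlaps a gene on the other strand, at 3.45 ± 0.35. Leukocyte markers had 1 of 10 higher (LAPTM5, 2.06 ± 0.19) and 0 lower, the same adjusted over the list alone (adjusted p = 0.797; median −0.062, mean −0.026, direction up). Lymphatic markers had 2 of 9 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.991; median 0.125, mean 0.306, direction down), with LYVE1 at −1.18 ± 0.28. Retinal glia, neuron and pigment epithelium markers had 0 of 7 called, also adjusted over the list alone (adjusted p = 0.98).

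The comparison of norrin with untreated cells asked which genes the FZD4 ligand moves. AXIN2, a direct Wnt/beta-catenin target, was at 0.862 ± 0.376 CPM in untreated and 1.88 ± 0.797 CPM in norrin libraries (1.14 ± 0.42 log2 units, n = 4 each), and APCDD1 at 0.897 ± 0.609 and 2.34 ± 0.563 CPM (1.37 ± 0.50). Neither passed: unadjusted p was 0.015 for AXIN2 and 0.0141 for APCDD1, and adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at least 0.759 for every gene. AXIN2 shares 25.2% of its exon bases with a gene on the same strand. In the authors' deposited table, AXIN2 had an RPKM of 0.301 untreated and 0.739 with norrin, a fold of 2.46. PLVAP (−1.01 ± 0.34), CLDN5 (−0.51 ± 0.37), TSPAN12 (0.40 ± 0.27), FZD8 (−0.72 ± 0.19), GJA4 (−1.22 ± 0.40), HEY2 (−1.75 ± 0.48), CXCL6 (2.81 ± 0.67) and IL1A (2.00 ± 0.51) did not pass either.

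At an adjusted p under 0.05, 0 genes were called for norrin by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0 by DESeq2, while 1066 (6.5%) had an unadjusted p under 0.05. The values of 647 genes (3.9%) did not overlap between the groups, where chance gives 2.86%. In simulated data for this comparison over 16169 genes, the same test called 21.2% of genes changed 2-fold and 90% of genes changed 4-fold, so changes near 2-fold could be missed. The changed genes had a mean above 1 CPM, and no transcript-length trend was simulated. These shares therefore do not cover lower genes and need not hold with that trend. Among lists, histone genes were lower (median −1.002, adjusted p = 6.22e-08; 0 of 23 members called, also adjusted over the list alone), but adjusted p = 0.337 with an estimated correlation. HIST1H4H was at −1.95 ± 0.56 and HIST1H1B at −2.19 ± 0.73. G2 and mitosis genes (median 0.22, adjusted p = 0.0182, and adjusted p = 0.768 with an estimated correlation) and cholesterol synthesis genes (0.16, adjusted p = 0.0166, and adjusted p = 0.492 with an estimated correlation) were higher as lists, with 0 members called, also adjusted over the list alone. CDK1 was at 0.64 ± 0.32 and IDI1 at 0.40 ± 0.16. Wnt/beta-catenin targets (median 0.02, camera adjusted p = 0.384), Notch pathway genes (0.0816, with 1 lower adjusted over the list alone), inflammatory genes (0.151, with 2 higher adjusted over the list alone) and p53 targets (0.162) did not pass. For Wnt/beta-catenin targets this covers 13 of 22 listed genes, since the others lay below the filter. Of 33 tested norrin receptor and Wnt pathway components 0 were called, and 1 was lower adjusted over the list alone.

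The combination was compared with untreated cells for the joint effect. RRAD rose by 9.15 ± 0.59 log2 units, DRAXIN by 7.63 ± 0.56, PARD6G by 5.04 ± 0.29, FAS by 4.46 ± 0.23, MDM2 by 4.63 ± 0.57 and CDKN1A by 3.72 ± 0.24, with MDM2 at 590.1 ± 251 CPM (n = 4). ICAM1 rose by 3.84 ± 0.23 and CXCL8 by 3.34 ± 0.22. MKI67 fell by 7.22 ± 0.43, KIF15 by 7.0 ± 0.52, HJURP by 6.75 ± 0.35, PLVAP by 4.77 ± 0.42 and SOX17 by 1.04 ± 0.18. GJA4 had 2 reads against 1246, a ratio of 581 with a counting interval from 161 to 4800. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2142 genes were higher and 2041 lower (25.4%), and 3563 (21.7%) did not overlap where chance gives 2.86%. The count of 4183 fell to 2106 with only the 2 groups compared and rose to 7310 with the transcript-length covariate. Of the p53 targets 49 were higher and 1 did not pass (49 adjusted over the list alone; camera adjusted p = 1.29e-32), and of the inflammatory genes 23 were higher and 2 lower, also adjusted over the list alone (9.29e-16). Of the G2 and mitosis genes 35 were lower and 1 did not pass (36 adjusted over the list alone; 2.38e-46), and of the DNA replication genes 36 were lower and 2 did not pass (36 lower and 1 higher adjusted over the list alone; 5.9e-36). Of the Notch pathway genes 9 were lower and 1 higher, also adjusted over the list alone (8.57e-05). Of the histone genes 9 were lower and 14 did not pass (11 adjusted over the list alone; adjusted p = 6.21e-05, and adjusted p = 0.549 with an estimated correlation). Wnt/beta-catenin targets did not pass (0.723).

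The nutlin-3 effect in the presence of norrin was read from the combination against norrin. RRAD rose by 10.37 ± 0.63, SUGCT by 5.26 ± 0.36, PLTP by 5.14 ± 0.29, MDM2 by 4.63 ± 0.57, CDKN1A by 3.83 ± 0.24 and ICAM1 by 3.61 ± 0.23. KIF15 (−7.43 ± 0.52), PBK (−7.02 ± 0.46), MKI67 (−6.98 ± 0.43), PLVAP (−3.76 ± 0.41) and CD34 (−2.0 ± 0.26) were lower, and GJA4 had 2 reads against 614, a ratio of 265 with a counting interval from 73 to 2190. Wnt/beta-catenin targets moved in both directions, with 2 of 13 higher, 3 lower and 8 not passing, also adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.98; median −0.06, mean −0.027, direction up). DKK1 (1.51 ± 0.16) and CD44 (1.30 ± 0.14) were higher. APCDD1 fell by 2.94 ± 0.54 to 0.300 ± 0.109 CPM from 2.34 ± 0.563 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000837), and AXIN2 was at 0.75 ± 0.3 CPM against 1.88 ± 0.797 CPM (−1.33 ± 0.42, adjusted p = 0.036). The AXIN2 call was lost with no filter (0.0587) and without norrin replicate 2 (0.111) or 3 (0.118) or combination replicate 1 (0.116) or 4 (0.0997). The interaction test of AXIN2 and APCDD1 did not pass, so a difference between the nutlin-3 effects with and without norrin was not shown for them.

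In that comparison 1584 genes were higher and 1499 lower (18.8%; edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and with library totals alone the split was 1268 higher and 1909 lower. The values of 3806 genes (23.2%) did not overlap, where chance gives 2.86%. The count of 3083 rose to 5717 with the transcript-length covariate, to 7023 with both covariates and to 5309 without the 2 libraries that stood apart. Of the p53 targets 48 were higher (49 adjusted over the list alone; camera adjusted p = 1.75e-36), and of the inflammatory genes 23 were higher and 2 lower (24 and 2 adjusted over the list alone; 1.79e-17). All 36 G2 and mitosis genes were lower, also adjusted over the list alone (1.08e-54), and of the DNA replication genes 36 were lower and 1 higher, also adjusted over the list alone (3.65e-40). Of the Notch pathway genes 8 were lower and 1 higher (9 and 2 adjusted over the list alone; 0.000588). Endothelial identity genes were lower, with 7 of 30 called (8 adjusted over the list alone; adjusted p = 0.0182, and adjusted p = 0.6 with an estimated correlation). Cholesterol synthesis genes were lower, with 7 lower and 1 higher of 24 (8 and 1 adjusted over the list alone; adjusted p = 0.00773, and adjusted p = 0.422 with an estimated correlation), among them SQLE (−1.03 ± 0.19) and IDI1 (−0.86 ± 0.16). Immediate early genes were higher, with 5 of 18 called, also adjusted over the list alone (adjusted p = 0.0397, and adjusted p = 0.375 with an estimated correlation), among them FOSL1 (1.37 ± 0.26). Histone genes did not pass (0.103).

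The norrin effect in the presence of nutlin-3 was read from the combination against nutlin-3. AXIN2 was at 0.75 ± 0.3 CPM with the combination and 0.681 ± 0.213 CPM with nutlin-3 alone (0.14 ± 0.43, n = 4 each). PLVAP (−0.66 ± 0.43), CXCL8 (0.43 ± 0.20), ASPM (1.19 ± 0.34), MCM10 (1.69 ± 0.46) and COL1A1 (2.57 ± 0.89) did not pass either. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, and 141 (0.9%) had an unadjusted p under 0.05. DESeq2 called 3, named after their values were seen: KTI12 (21.73 ± 3.77), NBL1 (−25.27 ± 4.2) and SUSD2 (−2.65 ± 0.56). None of the 3 was called by edgeR, and the values of KTI12 and NBL1 are not read as sizes of a change. Without nutlin-3 replicate 3, 1 gene, PIMREG, was called. The values of 140 genes (0.9%) did not overlap, where chance gives 2.86%. The share with an unadjusted p under 0.05 also lay below the 0.05 that unchanged genes would give. In simulated data for this comparison, without the transcript-length trend, edgeR called 17.5% of genes changed 2-fold, so changes near 2-fold could be missed. G2 and mitosis genes were higher (median 0.21, camera adjusted p = 0.00816, and adjusted p = 0.725 with an estimated correlation) and tip cell genes lower (−0.13, adjusted p = 0.014, and adjusted p = 0.781 with an estimated correlation), with 0 members called, also adjusted over the list alone. Wnt/beta-catenin targets (adjusted p = 0.957; median 0.023, mean −0.069, direction down), p53 targets (0.742) and inflammatory genes (0.576) did not pass.

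**Figure D3:**
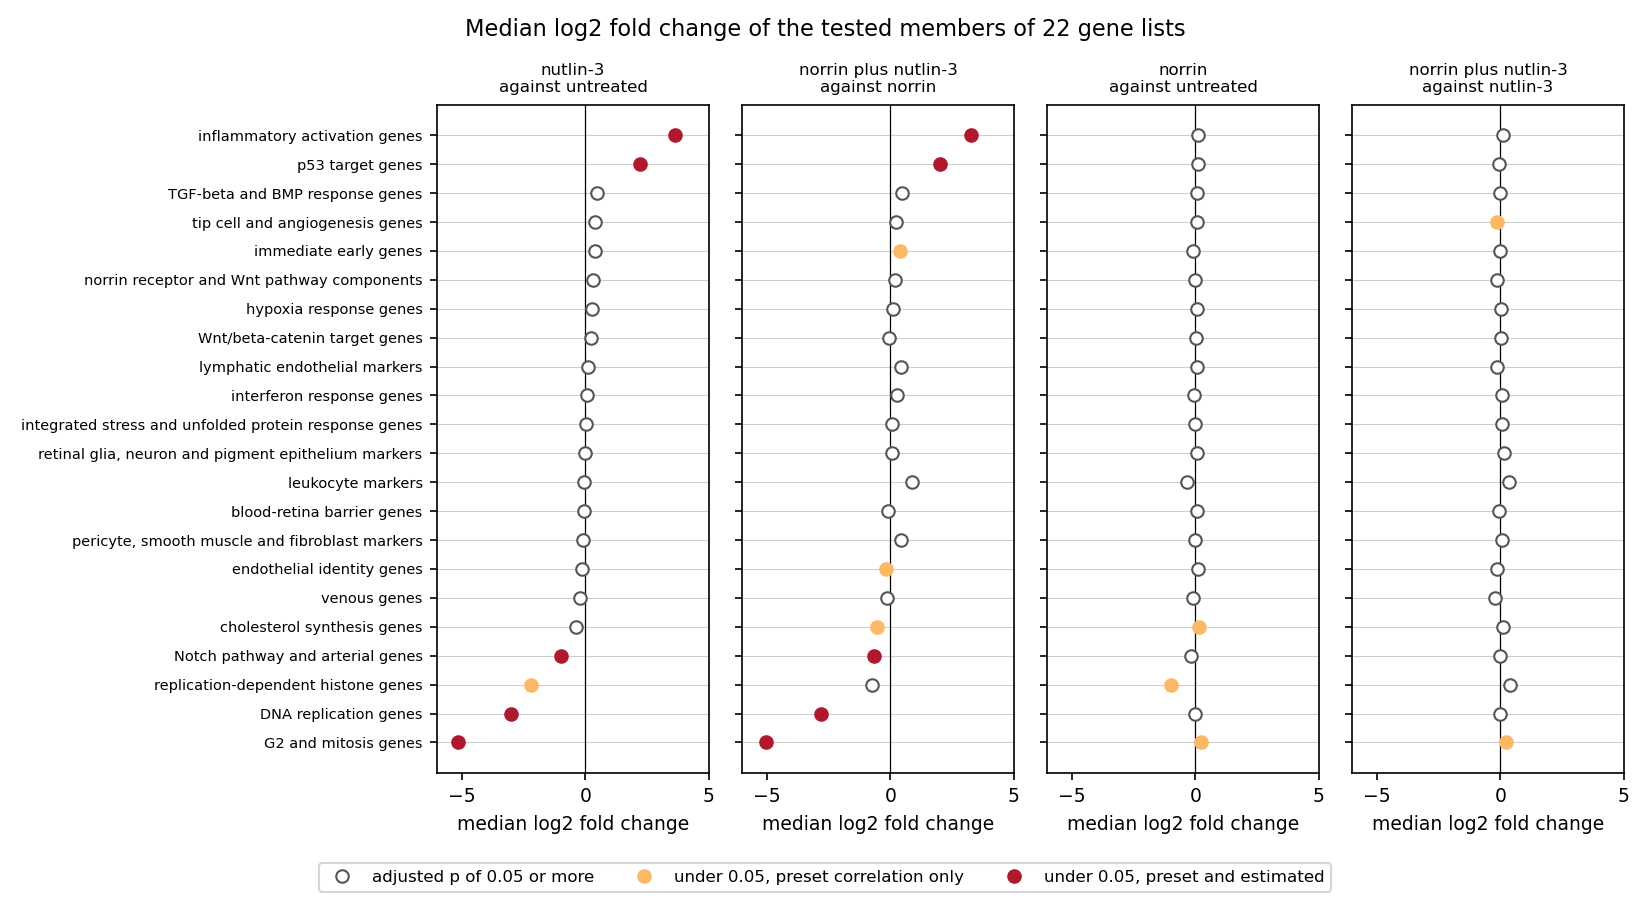
Median log2 fold change of the tested members of 22 gene lists in 4 comparisons, with filled points for lists past an adjusted p of 0.05 by camera. The median of G2 and mitosis genes is −5.15 for nutlin-3 against untreated and 0.22 for norrin against untreated.

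The interaction asked whether norrin acted differently when nutlin-3 was present. AXIN2 (−1.0 ± 0.60), APCDD1 (−1.17 ± 0.76), CXCL6 (−2.69 ± 0.79), IL1A (−2.07 ± 0.65), MCM10 (1.60 ± 0.53) and CLDN5 (0.87 ± 0.52) did not pass. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called (smallest adjusted p = 0.994). An unadjusted p under 0.05 was found for 427 (2.6%), below the share of 0.05 that unchanged genes would give. DESeq2 called 1 that edgeR did not (HIST1H2BI, 7.49 ± 1.49, named after its values were seen). Histone genes as a list were higher (median 1.29, camera adjusted p = 7.31e-08, and adjusted p = 0.337 with an estimated correlation), with 0 of 23 members called, also adjusted over the list alone; HIST1H1E was at 2.96 ± 1.12 and HIST1H1B at 2.84 ± 1.10. Wnt/beta-catenin targets (0.403), p53 targets (0.129) and inflammatory genes (0.384; median 0.065, mean −0.027, direction down) did not pass.

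Effects were then set against each other across genes, which are not independent replicates. The nutlin-3 effects with and without norrin share no library, and over the 4936 genes called in either comparison their log2 fold changes correlated with r = 0.92 (Spearman's rho 0.916, slope 0.869), with the same sign in 98.2%. The norrin effects with and without nutlin-3 also share no library. With 0 genes called in either, all 16437 were entered, and r was 0.044 (rho 0.049), with the same sign in 52.5%. This r was not stable in sign: it ranged from −0.066 without norrin replicate 1 to 0.139 without untreated replicate 4, and was also below 0 without untreated replicate 3 (−0.006) or combination replicate 3 (−0.014). Norrin and nutlin-3 effects against the same untreated libraries had 0 called genes in common in either direction, where chance gives 0. Their log2 fold changes, taken from mean CPM, had r = 0.286 and a covariance of 0.16, and the same sign in 65.0%. By edgeR r was 0.284 and the covariance 0.19. Simulated unchanged groups against those controls (20 simulations, mean CPM) gave r = 0.504, a covariance of 0.091 and the same sign in 66.8%. These held no nutlin-3 changes, so their r is not a chance level for the observed r. With the untreated libraries split into pairs, r by edgeR ranged from −0.062 to 0.159 and the covariance from −0.056 to 0.133. In 1 of the 6 splits, with untreated libraries 1 and 4 set against norrin, 1381 genes were called for norrin. Of these, 185 had the same and 115 the opposite direction as a nutlin-3 call. The other 5 splits called 0. Untreated libraries 1 and 4 had length slopes of −0.218 and −0.335 and GC slopes of 0.526 and 0.698. The other untreated libraries had length slopes of −0.068 and 0.102 and GC slopes of 0.326 and 0.334. The 1381 calls therefore cannot be told apart from these trends.

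**Figure D4:**
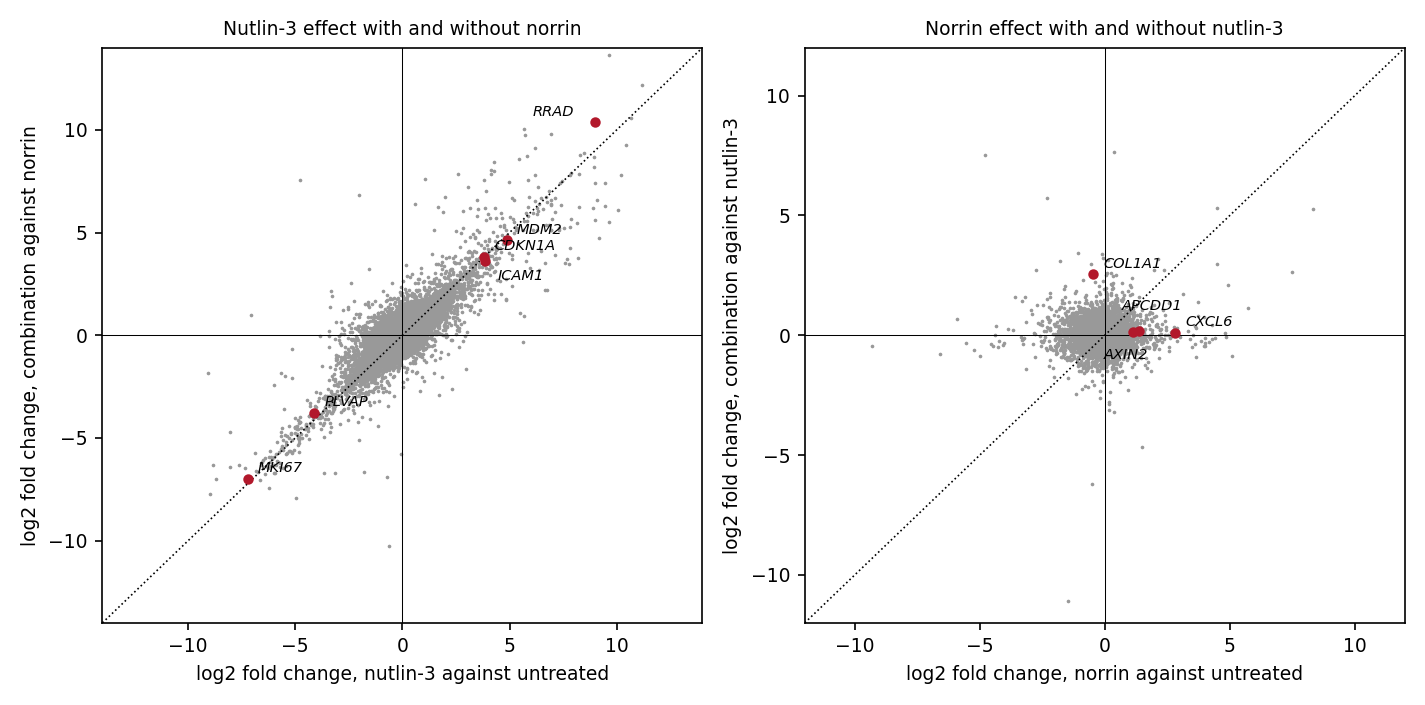
Log2 fold change of each tested gene for nutlin-3 without norrin (left, x axis) and with norrin (left, y axis), and for norrin without nutlin-3 (right, x axis) and with nutlin-3 (right, y axis), with the diagonal dotted and named genes in red. The correlation over all 16437 genes is 0.856 on the left and 0.044 on the right.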

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

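The tests of transcript-length and GC trends and of the libraries that stand apart, of SAT1, and of AFP in libraries given norrin were chosen after the results were seen, while the splits of the samples and the test of liver-type RNA were set before theirs.

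Single libraries stood far from the other 3 of their group in 12 of 92 tests of library measures and of gene levels. Chance gives about 4.6 for measures picked beforehand, but SAT1 and AFP, which gave some of the 12, were entered after their values were seen. The tests also share libraries, so 12 against 4.6 is not a test of an excess. Ribosomal RNA genes held 7.21% of counts in nutlin-3 replicate 4 (others 2.07% to 2.44%) and 8.26% in combination replicate 1 (1.87% to 2.67%). The transcript-length slope of combination replicate 2 was −0.623 (others 0.069 to 0.172), and its LRP5 level was 59.6 CPM (149 to 166). LRP5 was at 146 CPM in nutlin-3 replicate 2 (173 to 174), and MKI67 at 1.87 CPM in nutlin-3 replicate 3 (0.908 to 1.04). MDM4 was at 24.8 CPM (10.4 to 12.6) in nutlin-3 replicate 4. AFP was at 0.332 CPM in untreated replicate 1 and 0.0908 CPM in nutlin-3 replicate 4, with 0 in the others of those groups. There any single value above 0 meets the rule. The table's line without a gene name, which entered no comparison, averaged 45.6 ± 3.49 CPM with nutlin-3 and 41.6 ± 10.3 CPM with the combination, against 13.5 ± 3.96 CPM in untreated and 12.4 ± 3.92 CPM in norrin libraries, and its gene is not given. The norrin effect on histone genes differed with and without nutlin-3 (adjusted p = 7.31e-08), but not with an estimated correlation (0.337).

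No gene was called for norrin against untreated by edgeR or DESeq2, although 1066 had an unadjusted p under 0.05. If transcript-length and GC trends of the libraries hid broad changes, a fit with both trends as covariates would call at least 100 genes, and it called 1. Leaving out the libraries that stand apart, untreated replicate 4 and combination replicate 2, also called 1. The GC slope was 0.326 to 0.698 in untreated and 0.232 to 0.338 in norrin libraries. A GC covariate can therefore take up part of a norrin effect, so whether the GC trend hid broad changes is not decided. The fit with the length trend alone also called 1. This value and that without the 2 libraries argue against broad changes large enough to be called that the length trend or those libraries hid. Smaller ones stay open: with the length trend alone as covariate 3488 genes had an unadjusted p under 0.05, against 898 with both trends and 985 without the 2 libraries, and 2 of 35 splits had as many as 3488, the real one included (highest other 3513).

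That 1 gene was SAT1 (spermidine/spermine acetyltransferase), named after its values were seen. It was at 90.8 ± 29.95 CPM in untreated and 195 ± 28.6 CPM in norrin libraries (1.11 ± 0.27, adjusted p = 0.759), where norrin replicate 1 stood apart at 238 CPM (others 181 to 182), as did combination replicate 2 at 593 CPM (273 to 305). With both trends as covariates its log2 fold change was 1.13 ± 0.15 (edgeR adjusted p = 0.007, 0.000855 with the length trend alone, 0.0227 without the 2 libraries). SAT1 was picked because it passed in these fits, so they cannot count against the trends or those libraries as a cause. With library totals its log2 fold change was 1.29 ± 0.20, which argues against scaling as the whole cause. With the trends as covariates the fold barely moved and its estimated spread was smaller, while without the 2 libraries the fold was larger as well (1.32 ± 0.17). Chance is not excluded, as another split called 4 genes with the length covariate where the real one called 1 (5 of 35 splits called at least 1). With nutlin-3 present the norrin effect was 0.41 ± 0.27, and it fell to 0.0625 ± 0.2176 without combination replicate 2 and to 0.1606 ± 0.1199 with both trends as covariates (0.0598 to 0.5233 over its alternatives), so it rested largely on that library. A norrin response that also holds with nutlin-3 stays open, most of all a small one.

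Transcripts of liver, AFP among them, appeared in 3 of the 4 norrin libraries and in combination replicate 3. AFP was at 50.2 CPM in norrin replicate 1 (others 0 to 7.86) and ALB at 18 CPM, beside APOB at 9.47 and SERPINA1 at 8.61 CPM. In combination replicate 3 ALB was at 11.9 CPM, APOB at 1.96, APOA2 at 1.88 and AFP at 0.421 CPM. AFP passed 1 CPM in 3 of the 8 libraries given norrin, which argues against a rise of AFP by norrin with and without nutlin-3. These 3 were among the 4 norrin libraries, against 0 of 4 untreated. Norrin replicate 3 had 0 CPM of AFP, and likewise of ALB, APOA1, APOA2, SERPINA1, TTR, AHSG and FGB. AFP therefore rose neither alone nor in every norrin library. Whether norrin without nutlin-3 raised it in the others stays open. Of 25 further hepatocyte genes 21 were measured, and 57.1% (12) were higher in norrin replicate 1 than in every untreated and nutlin-3 library, between the bounds set for RNA of liver-type cells in norrin library 1, while 4 of the 21 also averaged above 1 CPM in untreated cells. All 10 of 10 abundant hepatocyte transcripts, a set that holds AFP and ALB, from which the pattern was seen, were higher there than in every untreated and nutlin-3 library, which goes with such RNA. A small amount of such RNA, which may have entered during handling, stays open, and no batch is given in the labels.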

How the results depend on the processing

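The covariates, the fit without the 2 libraries that stand apart, the removal of ribosomal RNA genes and the leave-outs of the correlations were chosen after the data were seen. Among the named genes, the covariates and the removal of ribosomal RNA genes were run only for SAT1. The fits of only the groups compared and the stricter thresholds were applied to counts of genes alone. Of 149 named-gene results, 115 were called, and 112 of these kept their call and direction under every alternative run for them. The exceptions were APCDD1 and SMOX (nutlin-3 against untreated) and AXIN2 (combination against norrin). Of the 34 not called, 30 kept that and their direction in all; CLDN5 and SAT1 passed in some, and MDM4 and AXIN2 were called in none but reversed. MDM4 with nutlin-3 reversed to −0.1866 without nutlin-3 replicate 4 and to −0.0015 without the 2 libraries, and AXIN2 in the combination against nutlin-3 to −0.1486 without combination replicate 3. Their leave-outs ranged from −0.1866 to 0.3113 (MDM4) and −0.1486 to 0.3571 (AXIN2). The reversed values lie within their SE; the cause was not tested. For nutlin-3 against untreated, length and GC covariates called 6655 genes, a 2-fold minimum 2813 and adjusted p under 0.01 2541, and leave-outs gave 3162 to 5034. For the combination against untreated, a fit of its own groups alone, with fewer samples and 15479 genes tested, gave 2106. The length covariate gave 7310, the 2-fold minimum 2566 and the stricter p 2395, and leave-outs 3210 to 5624. For the combination against norrin, the length covariate gave 5717, both covariates 7023, the fit without 2 libraries 5309 and the stricter p 1875, and leave-outs 2370 to 4423. Norrin against untreated gave 1 gene with the length covariate, 1 with both and 1 without the 2 libraries, and 0 in every leave-out. The combination against nutlin-3 gave 3 by DESeq2 and 0 to 1 over leave-outs, and the interaction 1 by DESeq2 and 0 in every leave-out. Except for the thresholds, the cause was not tested. Of 132 list tests 26 were called, 15 with an estimated correlation, 27 with the block and 32 by fry, which shared 20 of the 26, the other 6 being those for norrin against untreated, the combination against nutlin-3 and the interaction. Direction changed by fry in 11 of the 132, of which 0 had been called, and with the block in 6, of which 0 had. Among printed tests these were, for nutlin-3 against untreated, stress responses (fry 0.862), retinal markers (fry 0.991, block 0.998) and lymphatic markers (fry 0.982, block 0.998), and Wnt targets for the combination against nutlin-3 (block 0.998) and against norrin (block 0.998); 55 of the 132 were printed, a choice made with their directions known, and the cause was not tested. The nutlin-3 correlation was 0.856 over all genes and 0.874 to 0.92 over leave-outs. The norrin correlation ranged from −0.066 (without norrin replicate 1) to 0.139 (without untreated replicate 4), also reversing to −0.006 without untreated replicate 3 and −0.014 without combination replicate 3; the cause was not tested. Replicate numbers were not taken to pair the libraries, since not every same-number pair correlated over 0.1: 24 such pairs ranged from −0.478 to 0.509, with 13 over 0.1 (10.8 by chance, permutation p = 0.215), and 8 of 16 libraries matched their own number best (4 by chance, permutation p = 0.0457, over all 13824 assignments of the numbers). Some shared structure by number is not excluded. The permutations were added after these counts were seen. The replicate block called 4702 genes for nutlin-3 against untreated (4283 shared), 4418 for the combination against untreated and 3133 against norrin, and 0 in the other 3 comparisons. It also called the histone list for the combination against norrin (0.0499). Depth limits the low genes: AXIN2, APCDD1 and the histones lay near 1 CPM, and LEF1 and NKD1 below the filter.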

Other observations

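The 8 lists tested here and the relation of the histone list to library measures were chosen after the data were seen.

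Fanconi anaemia and homologous recombination genes fell with nutlin-3 as replication genes did; other DNA repair genes were not tested as a list. BRCA1 was at −3.86 ± 0.26, FANCD2 at −4.08 ± 0.27 and FANCA at −3.57 ± 0.29, and of 22 listed 19 were lower and 3 did not pass (19 adjusted over the list alone; median −3.21; camera with Benjamini-Hochberg adjustment over 48 added tests, adjusted p = 1.24e-16, and adjusted p = 0.00567 with an estimated correlation). Lysosome genes were higher, with LAMP1 at 0.84 ± 0.17, LAMP2 at 0.89 ± 0.23 and CTSB at 0.89 ± 0.16 and 1, GLA, lower (−0.94 ± 0.22). Of 23, 7 were higher (adjusted p = 0.0413, and adjusted p = 0.947 with an estimated correlation). The polyamine genes SAT1 (1.59 ± 0.27) and SMOX (0.74 ± 0.23) were higher and ODC1 (−1.18 ± 0.22) lower; of the 16 listed, 2 were higher and 5 lower, and the list did not pass (0.449). The SMOX call was lost without untreated replicate 2 (adjusted p = 0.0712) or 3 (0.0649) or nutlin-3 replicate 1 (0.0705; edgeR quasi-likelihood with Benjamini-Hochberg adjustment). TAP1 (2.77 ± 0.17) and B2M (1.01 ± 0.27), of antigen presentation, were higher, and their list of 17, with 4 higher and 1 lower, did not pass (0.381), nor did NKG2D ligands (0.499; ULBP3 at −1.71 ± 0.40 against ULBP1 higher), connexins (0.8), mitochondrial DNA-encoded genes (0.8) and ribosomal protein genes (0.754). In the other comparisons, Fanconi anaemia and homologous recombination genes (lower) and lysosome genes (higher) passed for the combination against untreated (8.46e-17 and 0.0306) and against norrin (4.52e-21 and 0.0306), antigen presentation genes were higher for the combination against norrin (0.0497), and ribosomal protein genes were higher for the combination against nutlin-3 (0.013). With an estimated correlation the Fanconi anaemia and homologous recombination genes passed (0.00567 and 0.00543) and the other lists did not (0.947 each).

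The histone list followed the transcript-length slope of the libraries within groups. Its mean was −0.25 ± 0.84 log2 CPM in untreated, −1.11 ± 0.38 in norrin, −1.92 ± 0.27 in nutlin-3 and −1.81 ± 0.57 in combination libraries (n = 4 each). Across the 16 libraries, after group means were removed, it correlated with the transcript-length slope (r = −0.74, permutation p = 0.0011, Benjamini-Hochberg 0.0033 over 3 measures; rho −0.79, permutation p = 0.00026), and r was −0.64 without the 2 farthest libraries. It did not with the GC slope (r = 0.16, permutation p = 0.57, and rho 0.13, permutation p = 0.64) or the ribosomal share (r = 0.43, permutation p = 0.097, and rho 0.33, permutation p = 0.21). The permutations moved the centred values over all 16 libraries rather than within groups, so these p-values are approximate and may be too small.

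Other splits of the libraries tested whether chance could give the counts of called genes. For nutlin-3 against untreated the count argues against chance: the real split called 4435 genes and the highest of the other splits 0. That is 1 of 35 splits, the smallest share that 35 splits allow. The same holds for the combination against norrin, with 3083 genes against 349 (1 of 35). For the combination against untreated the count does not exclude chance. The split that exchanged untreated replicate 3 with combination replicate 2 called 4635 genes against 4183 (2 of 35). Combination replicate 2 stood apart in transcript length, a structure of the libraries. Lists fixed beforehand argue against chance for their own genes. Of 50 p53 targets 49 were higher, and of 36 G2 and mitosis genes 35 were lower (camera with an estimated correlation, adjusted p = 0.000281 and 0.000431). For norrin against untreated and the combination against nutlin-3 the real splits called 0 and the highest others 1 (35 of 35 each), and for the interaction 0 and 0 (100 of 100 drawn). With 0 calls in the real split each other split calls as many, so these 3 counts decide nothing.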
